A study of Homo sapiens with 3 samples.

How the data were processed

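Droplet single-cell RNA sequencing libraries were made from 3D cultures on days 0, 10 and 20, with 1 library per day. The submitters' processing notes name Cell Ranger 5.0.1 and genome build hg38. The deposited values are a signal, the mean normalised expression per cluster as averaged by the authors, given as a table for each day and a table of 24 clusters for the whole series. Every column was checked to total 10000, with no negative values, and was read as linear. The columns of the table of the whole series name clusters and no library. Cell and gene filters, doublet treatment, the averaging tool, clustering settings and cell numbers are not given in the sources used here. No counts were used, so the depth per library is unknown and no counting interval was computed.

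Of 17505 gene symbols, 17255 matched the reference names and 16794 had one position in GENCODE 29, from which positions and the longest transcript per gene were taken. The 3 day tables share 15471 genes, and each comparison used the genes listed on both of its days (15924 for day 10 against day 0, 15863 for day 20 against day 10 and 15577 for day 20 against day 0). The day value was the unweighted mean over clusters. Log2 ratios used a pseudocount of 0.1, and genes were counted when the larger day value was at least 1 per 10000 and the ratio at least 2-fold. With 1 library per day, neither cells nor clusters stood in as replicates, and no test was run.

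For each comparison the named genes were the 10 with the largest positive and the 10 with the largest negative log2 ratio, among genes at the floor whose clusters did not overlap between the days, and not all of them are printed. Mitochondrial, ribosomal protein and sex chromosome marker genes were left out. From each list up to 4 members were named, those with the highest values and the largest ratios at the floor, and from each cluster up to 5 of its top 10 genes. A few genes outside this rule, such as ISG15, IFI6 and MX1 in day 0 cluster 7 and KRT5 and KRT19 in day 20 cluster 7, were chosen after their values were seen.

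There were 31 gene lists, 16 of cell type markers and 15 of gene groups. For each, the median log2 ratio of the measured members was set among 10000 random lists of the same size matched on mean expression in 20 bins, and was called beyond percentile 2.5 or 97.5. The lists, the named-gene rule, the floor, the thresholds and a first set of other settings were fixed before the data were examined. A day cluster was named after the cell type list with the most markers enriched against the mean of the other clusters. At least 3 such markers were needed, and a tie with another list left the cluster unnamed. That list also had to have more markers than any other cell type list among the cluster's top 10 genes. The condition on the top 10 genes was set after the leading genes had been seen.

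Cell shares per cluster were estimated, since the same cells form the day clusters and the clusters of the whole series, by the weights that make the weighted sums of both sets equal over 15470 genes. The median residual was 0.0634% per gene. All 33 successive pairs of day clusters had falling shares, as clusters numbered by size would, but only 18 of the 23 pairs of clusters of the whole series did. Over resampled genes the largest SD of a share was 0.177 percentage points for day clusters and 0.650 for clusters of the whole series, so the shares are approximate. On simulated cells with 13644 genes, which hold no model error, the largest error of a share was 0.000887 percentage points. Simulated tables with known changes were used to test the counts and lists. Over 15924, 15863 and 15577 genes, 50 of 50 genes made 4-fold higher and 50 of 50 made 4-fold lower were recovered in each comparison, and of 200 unchanged random lists 5%, 3% and 6% were called. The simulated later day was resampled from clusters of the earlier day with small noise, and changed genes lay above the floor. It held no library effect, length trend or co-regulated lists. Recovery at the 2-fold threshold was thus bound to be full, and checks the code rather than the error in these libraries.

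The other settings fixed at that time were larger and smaller pseudocounts, the median over clusters, leaving out each cluster, leaving out proliferating or non-epithelial clusters, rescaled columns, removal of mitochondrial and ribosomal protein genes, no floor or a higher floor, a 4-fold threshold, list members at the floor, 10 expression bins and the mean of members. For cluster names another reference, pseudocount and floor were tried, for ranges over clusters the farthest cluster was left out, and clusters of the whole series were related to day clusters over genes at the floor too. Alternatives chosen after seeing the data were weighting by estimated cell shares, centring on the median gene, leaving out day 10 cluster 11, removing the length trend in 20 bins, with and without the median shift, and random lists matched also on transcript length in 4 classes. Weighting by given cell numbers and the use of columns naming the day were not run, since the tables used here hold neither. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.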

Results

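Human lacrimal gland-like organoids were profiled by droplet single-cell RNA sequencing. They were grown from 201B7, an established induced pluripotent stem cell line, through 10 weeks of differentiation, sorting of gland-like progenitors by flow cytometry and 3D culture in Matrigel, a basement membrane gel. There was 1 library from each of days 0, 10 and 20 of the 3D culture. The values are mean normalised expression per cell cluster on a linear scale, on which each cluster totals 10000, for 8 clusters on day 0, 20 on day 10 and 8 on day 20. The day tables list 16512, 16762 and 16124 genes. No read or molecule counts were used, so the depth behind each value is unknown. A day value here is the unweighted mean over the clusters of that day, log2 ratios were taken after adding 0.1 to each day value, and counts cover genes that reached 1 per 10000 on either day. With 1 library per day there is no replicate error, so differences are described by size only. A gene list is called higher or lower when its median log2 ratio lay outside the central 95% of 10000 random lists, which describes these libraries and tests nothing about the culture days.

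The comparison of day 10 with day 0 asks what differed between organoids and the sorted progenitors they came from. KRT6A, a keratin of activated and stratifying epithelium, averaged 0.0847 on day 0 and 10.0 on day 10, a log2 ratio of 5.78. FOSB, a subunit of the AP-1 transcription factor, went from 0.111 to 4.84 (log2 ratio 4.55). DCN, which encodes the matrix proteoglycan decorin, was at 4.12 on day 0 and 0.0915 on day 10 (log2 ratio -4.46). CXCL14, an epithelial chemokine, was at 84.9 on day 0 and 6.21 on day 10 (log2 ratio -3.75). KRT6A lies on chromosome 12 from 52487174 to 52493257, FOSB on chromosome 19 from 45467995 to 45475179, DCN on chromosome 12 from 91140484 to 91183123 and CXCL14 on chromosome 5 from 135570679 to 135579279 (GRCh38, the build also called hg38).

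Of 1705 genes at the floor, 233 were at least 2-fold higher and 111 at least 2-fold lower on day 10. In 140 and 81 of these, respectively, no cluster of one day overlapped the range of the other day. Among these, SERPINB1, a protease inhibitor, had a log2 ratio of 4.45, DSG1, a desmosomal cadherin, 3.93, SCEL, a component of the cornified envelope, 3.76, and SPINK5, a protease inhibitor of stratified epithelium, 3.53. CCN1, a matricellular protein, stood at 3.67, ALDH3A1, an abundant corneal enzyme, at 3.61, ATF3, a stress-induced transcription factor, at 3.52, and COMP, a matrix glycoprotein, at 3.43. Of the genes lower on day 10, ISG15, an interferon-induced ubiquitin-like protein, had a log2 ratio of -4.32, PLTP, a phospholipid transfer protein, -2.47, and DEGS1, a ceramide synthesis enzyme, -2.27. FTL, the ferritin light chain, stood at -1.81, MAGED2 at -1.77, MIR205HG, the host transcript of a microRNA of basal epithelium, at -1.75 and BCAM, a laminin receptor, at -1.66. The median log2 ratio of genes at the floor was -0.21, and with ratios centred on it the higher genes made up 85.8% of the 2-fold differences in place of 67.7%.

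The ductal, basal and corneal marker lists were higher on day 10. The ductal list had a median log2 ratio of 1.23. Of its 12 members at the floor, 8 were at least 2-fold higher and 1 at least 2-fold lower. The higher ones included KRT7 at 2.42 and KLF6, a transcription factor also on the early response list, at 2.70. KRT19 was at 82.5 and 79.5. The basal list had a median of 1.23. KRT14 went from 0.172 to 3.68 and KRT5 from 43.7 to 66.8, while KRT15, a keratin of epithelial progenitors, was at 18.1 on day 0 and 1.99 on day 10. The corneal list had a median of 0.65, and KRT12, a keratin of corneal epithelium, had a log2 ratio of 2.28. The stratified keratinocyte list had a small median of 0.18, and its call ended without any one of day 0 clusters 1 and 6 or day 10 clusters 8, 12, 18 and 19. Tear film and mucosal antimicrobial genes, 10 of 18 measured, had a median of 0.68, or 0.25 with clusters weighted by their estimated share of cells. Among them 1 member, S100A9, an antimicrobial calcium-binding protein, reached the floor.

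Early response genes formed the list with the largest positive shift. Their median log2 ratio was 1.89, with 8 of the 12 members at the floor at least 2-fold higher, and every day 10 cluster had a higher list mean than every day 0 cluster. FOS went from 1.62 to 12.2 and JUN from 1.13 to 6.44, both AP-1 subunits. Interferon response genes were lower, with a median of -2.42, or -1.36 with clusters weighted by estimated share. Day 0 cluster 7, an estimated 1.41% of the day 0 cells, had ISG15 at 22.5, IFI6 at 13.6 and MX1, an antiviral GTPase, at 5.66, against means of 2.30, 1.90 and 0.360 over the other day 0 clusters. IFI6 averaged 3.37 on day 0 and 0.341 on day 10.

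Matrix, NOTCH and FGF lists were higher on day 10. The basement membrane and matrix list had a median of 0.57, with FN1, which encodes fibronectin, going from 1.62 to 9.54 and COL17A1, a hemidesmosome collagen, from 1.43 to 6.05. Its call ended against random lists matched on transcript length. The NOTCH pathway list had a median of 0.54, with JAG1, a NOTCH ligand, at 1.44, and the FGF response list 0.45, with EGR1 at 2.44. Both calls ended without day 0 cluster 5 and with members at the floor. The FGF call also ended with the larger pseudocount, with the mean of members, with clusters weighted by estimated share and against random lists matched on transcript length, and the NOTCH call with both other pseudocounts and the median over clusters. The small retina and pigment epithelium list was lower, with a median of -0.12 over 4 genes below the floor, and this call too ended without day 0 cluster 5.

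Mitochondrially encoded genes were higher on day 10, with a median of 0.49, and made up a mean of 12.5% of the values against 9.54% on day 0. Ribosomal protein genes made up 14.4% on day 10 and 19.0% on day 0. Transcript length moved with the same contrast. Spearman's rho of the log2 ratio with the longest annotated transcript was 0.49. It was taken over 1582 genes at the floor with a known length, without mitochondrial and ribosomal protein genes. With the length trend removed and the median shift kept, 55 of the 111 lower genes and 137 of the 233 higher genes stayed at least 2-fold apart. The counts were then 150 higher and 124 lower genes, and 204 and 71 with the median shift removed too. Genes are not independent replicates, so no p is given.

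The other lists were not called for day 10 against day 0. Gland bud transcription factors had a median of -0.06, with PAX6, a master regulator of eye development, at 8.88 and 6.06, and FOXC1 at 2.32 and 1.38. Acinar secretory genes, 7 of 19 measured, had a median of 0.03 with no member at the floor, myoepithelium 0.05 and the conjunctival list 0.02. Fluid and ion transport had 0.13, with AQP3, a water and glycerol channel, at 22.9 and 15.1. Hypoxia and glycolysis had 0.41, cholesterol synthesis 0.45, the endoplasmic reticulum and secretory pathway -0.25, BMP response -0.017, WNT response -0.10, p53 response -0.22 and cytosolic ribosomal proteins -0.39. Against random lists matched on transcript length too, hypoxia and cholesterol synthesis were called higher and WNT response lower. Proliferation had 0.17, or 0.91 and called higher with clusters weighted by estimated share. Pluripotency (0.0013), neural (-0.028), lens (0.0021), mesenchyme (0.28), endothelium (0.031) and immune (-0.010) genes were also within the range of random lists. TUBB3, a neuronal tubulin, was at 6.78 on day 0 and 2.55 on day 10.

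**Figure D1:**
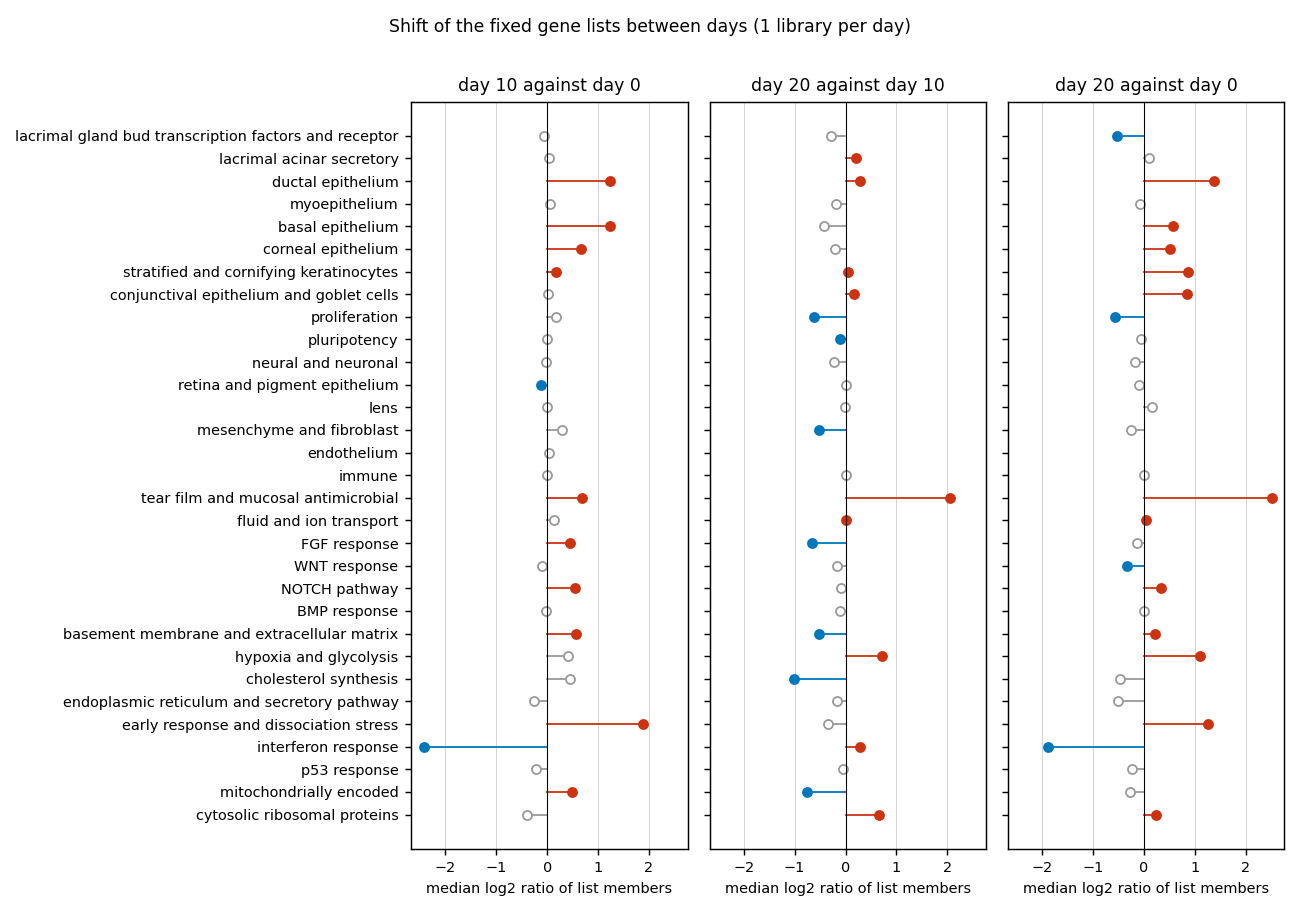
Median log2 ratio of each fixed gene list (horizontal axis) in each of the 3 comparisons, with filled points for lists outside the central 95% of random lists, red for higher and blue for lower. Early response genes stood at 1.89 and interferon response genes at -2.42 for day 10 against day 0.

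The comparison of day 20 with day 10 asks what differed within the 3D culture. Genes induced by low oxygen were higher on day 20, led by EGLN3, an oxygen-sensing prolyl hydroxylase, at 0.126 on day 10 and 1.73 on day 20 (log2 ratio 3.02). Cholesterol synthesis genes were lower, among them HMGCS1, the enzyme that makes HMG-CoA, at 2.59 and 0.630 (log2 ratio -1.88). H1-4, a linker histone, had the largest negative log2 ratio among the genes without cluster overlap, -2.80. EGLN3 lies on chromosome 14 from 33924231 to 34462774, and HMGCS1 on chromosome 5 from 43289395 to 43313512.

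Of 1526 genes at the floor, 53 were at least 2-fold higher and 124 at least 2-fold lower on day 20, of which 30 and 57 had no overlap between the clusters of the days. The higher genes included DDIT4, a stress-induced inhibitor of mTOR signalling, with a log2 ratio of 1.56, FAM162A at 1.25 and C4orf3 at 1.33. ZFAS1, a noncoding host transcript of small nucleolar RNAs, stood at 1.36, ANKRD37, a hypoxia target, at 1.30 and COX7C, a subunit of cytochrome c oxidase, at 1.23. TOMM7, a subunit of the mitochondrial import complex, had a log2 ratio of 1.26, TMEM256 1.13 and SEC61G, a subunit of the protein translocation channel, 1.12. With the length trend removed and the median shift kept, ZFAS1 (0.98), ANKRD37 (0.98), COX7C (0.96), TOMM7 (0.70), TMEM256 (0.50) and SEC61G (0.73) lay below 2-fold. The lower genes included CYP51A1, a sterol demethylase, at -1.87, WEE1, a cell cycle checkpoint kinase, at -1.67 and HSPA4, a chaperone, at -1.43. FAT1, a large cadherin, stood at -1.79, PRPF4B, a splicing kinase, at -1.50, VCL, which encodes vinculin, at -1.39 and CTNNB1, which encodes beta-catenin, at -1.34. VCL lay within 2-fold with the length trend removed and the median shift kept (-0.88), and PRPF4B (-0.87), CTNNB1 (-0.95) and FAT1 did so when the median shift was removed too. The median log2 ratio was -0.14, and centring on it changed the share of higher genes from 29.9% to 53.3%.

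The hypoxia and glycolysis list had a median of 0.72, with 4 of 8 members at the floor at least 2-fold higher. NDRG1, a hypoxia-induced gene, went from 0.513 to 2.19 and LDHA, which encodes lactate dehydrogenase, from 16.8 to 24.3. The cholesterol synthesis list had a median of -1.02, with 8 of 10 members at the floor at least 2-fold lower and none higher. Proliferation genes had a median of -0.63 with none at the floor, or -1.28 with clusters weighted by estimated share. FGF response genes had a median of -0.65, with DUSP4, a MAP kinase phosphatase, at -1.01, a call lost among the 4 members at the floor. Basement membrane genes had -0.51, with LAMB1, a laminin chain, at -1.56 and COL17A1 at 6.05 and 4.21. This matrix call ended without any one of day 10 clusters 1, 11 and 15 or day 20 clusters 0, 1, 4 and 7, and against random lists matched on length. Mesenchyme genes had -0.51, a call that ended without day 10 cluster 16, against random lists matched on length and, at -0.33, with clusters weighted by estimated share.

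Several higher calls rested on day 20 cluster 7, an estimated 1.86% of the day 20 cells. Tear film and mucosal antimicrobial genes, 10 of 18 measured, had a median of 2.05 with this cluster and -0.14 without it. With clusters weighted by estimated share the median was 0.43. S100A9 averaged 4.35 on day 10 and 25.2 on day 20, S100A8 0.558 and 8.53, and LCN2, an iron-sequestering lipocalin of mucosal secretions, 0.0921 and 5.12. These means are unweighted over 20 clusters on day 10 and 8 on day 20, so a small cluster counts for more on day 20. S100A9 was at 201 in day 20 cluster 7, and at 52.0 in day 10 cluster 13, an estimated 1.77% of the day 10 cells. The ductal list had 0.28 with cluster 7 and -0.12 without it, and the conjunctival list 0.17 and -0.071, or 0.079 with that weighting. The ductal call also ended without day 20 cluster 2. Of the 13 ductal members at the floor, 1 was at least 2-fold higher and 2 at least 2-fold lower. The acinar secretory list, whose 8 measured members all lay below the floor, had 0.20, or 0.060 with that weighting, and the interferon response list 0.29, or -0.12 with it, and both calls ended without cluster 7. Fluid and ion transport had a median of 0.011, which was called but ended without that cluster and without 8 other single clusters. The stratified keratinocyte list had 0.057 and pluripotency -0.11, and both calls ended without any one of several single clusters, day 10 cluster 11 among them.

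Mitochondrially encoded genes had a median of -0.75 and cytosolic ribosomal proteins 0.65, and the days did not overlap over clusters for either list. MT-ATP6, a subunit of ATP synthase, was at 218 on day 10 and 100.3 on day 20, and RPLP1, a ribosomal stalk protein, at 40.2 and 71.8. Mean shares on day 20 were 8.02% mitochondrial and 23.6% ribosomal. Spearman's rho of the log2 ratio with transcript length was -0.56 over 1408 genes, again without mitochondrial and ribosomal protein genes. The sign was opposite to that of day 10 against day 0, and the day 10 library enters both comparisons. With the length trend removed and the median shift kept, 57 of the 124 lower genes and 27 of the 53 higher genes stayed at least 2-fold apart, and the counts were 38 higher and 72 lower. With the median shift removed too they were 62 higher and 39 lower, so the majority turned to higher genes (61.4%).

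**Figure D2:**
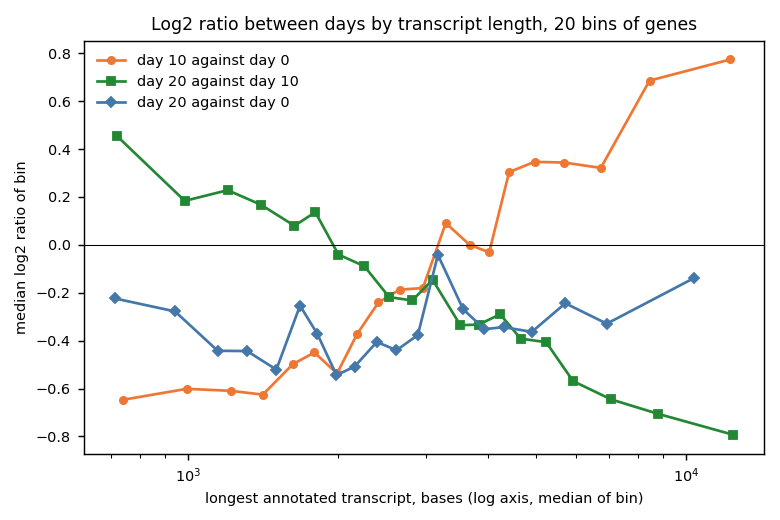
Median log2 ratio (vertical axis) of genes in 20 bins of longest annotated transcript, in bases on a log axis, for the 3 comparisons. Genes at the floor were used, without mitochondrial and ribosomal protein genes. Spearman's rho over genes was 0.49 for day 10 against day 0, -0.56 for day 20 against day 10 and 0.048 for day 20 against day 0.

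The remaining lists were not called for day 20 against day 10. Basal epithelium had a median of -0.43, with KRT15 going from 1.99 to 5.16, and was called lower at -0.66 with clusters weighted by estimated share. Early response genes had -0.34, with KLF6 at -1.33 and JUNB at 1.02, and were called lower with that weighting (-0.43) and against random lists matched on transcript length too. Gland bud transcription factors had -0.28, corneal epithelium -0.21, myoepithelium -0.18, neural genes -0.22, retina 0.015, lens -0.0083, immune 0.0064, WNT response -0.16 (called lower at -0.18 with that weighting), NOTCH pathway -0.096, BMP response -0.10, the secretory pathway -0.17 and p53 response -0.054. HSPA5, the main chaperone of the endoplasmic reticulum, was at 3.51 on day 10 and 1.45 on day 20. Endothelium had 2 measured genes, too few for a value.

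The comparison of day 20 with day 0 spans the whole 3D culture. KRT6A had the largest positive log2 ratio among genes without cluster overlap, 6.69, from 0.0847 to 18.9. SERPINB1 followed at 5.26, and ADIRF, an adipogenesis regulator, went from 1.58 to 33.0 (log2 ratio 4.31). S100A4, a calcium-binding protein of motile cells, went from 7.57 to 82.8 (3.44). DCN (-4.97), CXCL14 (-4.73, from 84.9 to 3.10) and ISG15 (-3.52) had the largest negative ratios among such genes.

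Of 1532 genes at the floor, 144 were at least 2-fold higher and 188 at least 2-fold lower, of which 70 and 131 had no overlap between clusters. The higher genes also included SPINK5 at 4.36, FOSB at 4.22, FAM83A at 3.35, SCEL at 3.29, LEMD1 at 3.16 and AHNAK2, a very large scaffold protein, at 3.08. The lower genes included KIF5C, a neuronal kinesin, at -3.25, PLTP at -2.81, TSC22D1 at -2.70, ODC1, the first enzyme of polyamine synthesis, at -2.61, DEGS1 at -2.55 and NUP93, a nuclear pore protein, at -2.40. The median log2 ratio was -0.29, and centring on it changed the share of higher genes from 43.4% to 68.7%. With the length trend removed and the median shift kept, 138 of the 144 higher and 172 of the 188 lower genes stayed at least 2-fold apart. With the median shift removed too, all 144 higher but only 75 of the 188 lower genes did so. The counts were then 208 higher and 75 lower, so that 73.5% were higher.

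The ductal list had a median of 1.38, with 7 of 12 members at the floor at least 2-fold higher and 1 at least 2-fold lower. KRT23 went from 0.212 to 1.43, and KRT8 was at 10.3 and 3.06. The basal list had 0.57, with KRT14 at 0.172 and 5.68, ITGB4, a hemidesmosome integrin, at 0.430 and 2.31, and KRT15 at 18.1 and 5.16. The stratified keratinocyte list had 0.86, with DSG1 at 3.19, and the days did not overlap over clusters. With clusters weighted by estimated share the basal, stratified and corneal lists stayed called at 0.36, 0.50 and 0.97. The corneal list had 0.51, with KRT12 at 1.83, and its call ended without day 20 cluster 0 and with the mean of members. Hypoxia and glycolysis had a median of 1.10 and early response genes 1.25, both with a higher list mean in each day 20 cluster than in each day 0 cluster. NDRG1 stood at 2.60, FOS at 2.13 and JUN at 2.40. Interferon response genes had -1.88, or -1.26 with that weighting, and WNT response genes -0.33, the second with no member at the floor. The NOTCH list had 0.34, with NRARP, a NOTCH target, at 2.33, and cytosolic ribosomal proteins had 0.24. The first call ended with the median over clusters and the second with the mean of members. Basement membrane genes had 0.21, a call that ended without day 20 cluster 5, with the median over clusters (-0.14) and, at 0.026, with clusters weighted by estimated share.

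Gland bud transcription factors were lower on day 20 than on day 0, with a median of -0.54. PAX6 was at 8.88 and 5.49 and FOXC1 at 2.32 and 1.10. The call ended without day 20 cluster 6, without the proliferating clusters of both days, with members at the floor and with the mean of members. Of the 18 tear film genes, 10 were measured. Tear film genes had a median of 2.51 and the conjunctival list 0.84, and without day 20 cluster 7 these were -0.022 and -0.053. With clusters weighted by estimated share the same lists had 0.80 and 0.099. Fluid and ion transport had 0.034, and its call ended without cluster 7 and without 7 other single clusters. Proliferation genes had -0.57, a call that ended without the proliferating clusters of both days and, at -0.25, with clusters weighted by estimated share. The median rested on the single proliferating cluster of each day, at 0.97 without day 0 cluster 6 and -1.71 without day 20 cluster 6.

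The lists not called for day 20 against day 0 were acinar secretory genes (median 0.092), myoepithelium (-0.085), pluripotency (-0.048), neural genes (-0.17), retina (-0.089), lens (0.16, called higher at 0.24 with that weighting), mesenchyme (-0.26), immune (0.012), FGF response (-0.14), BMP response (-0.0070), cholesterol synthesis (-0.47, called lower at -0.66 with it), the secretory pathway (-0.50), p53 response (-0.23) and mitochondrially encoded genes (-0.28). Of the 19 acinar secretory genes, 8 were measured and none reached the floor. SEC61B, a subunit of the protein translocation channel, was at 5.68 on day 0 and 2.23 on day 20. ID1, a BMP target, was at 4.95 and 10.1, and BMP7 at 1.19 and 0.344.

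**Figure D3:**
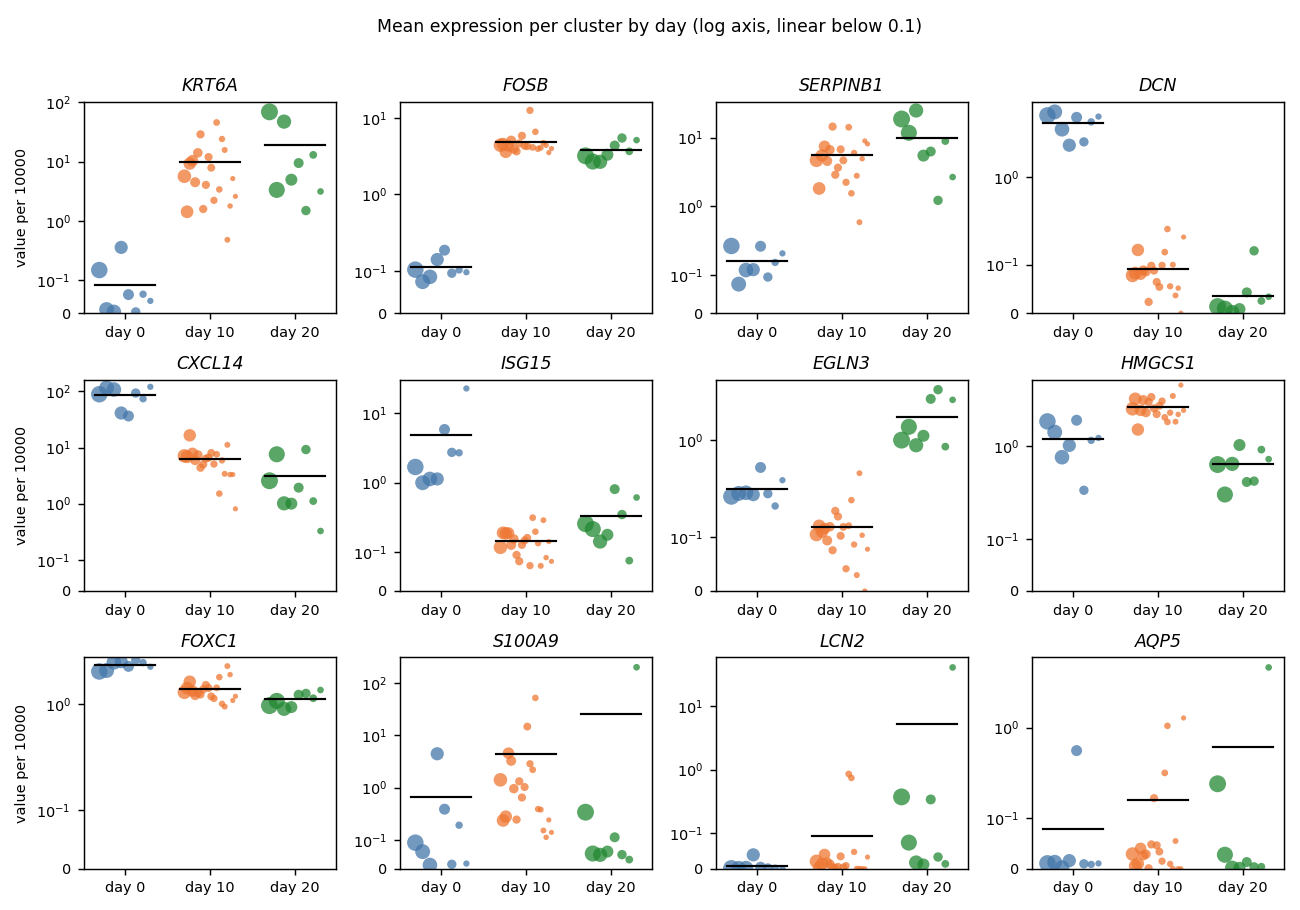
Mean expression per 10000 (vertical axis, log above 0.1) of 12 genes in each cluster, by day, with point size by estimated share of cells and a line at the unweighted mean. KRT6A averaged 0.0847 on day 0, 10.0 on day 10 and 18.9 on day 20, and S100A9 reached 201 in day 20 cluster 7.

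Within each day the clusters were described by their genes, and 9 of the 36 day clusters met the naming rule. Others had at least 3 enriched markers of a list that did not lead their top 10 genes. Day 10 cluster 11 and day 20 cluster 5, with 6 and 5 basal markers, were among them. So was day 10 cluster 17, with 3 proliferation markers, which therefore stayed in where proliferating clusters were left out. Proliferation markers named day 0 cluster 6 (12 markers, led by CENPF at 6.21 and UBE2C at 5.39), day 10 clusters 7 and 8 (13 and 10 markers) and day 20 cluster 6 (10 markers, with MKI67 at 1.86). The clusters named stratified keratinocyte-like were day 10 clusters 6 and 14 and day 20 cluster 0. In the last, KRT6A was at 68.9 and SPRR1B, a cornified envelope precursor, at 6.08. Day 10 cluster 12 went unnamed, since its 5 stratified and 5 ductal markers tied. Its top 10 genes held the stratified markers SPRR1B at 10.6 and IVL at 4.25, and no ductal marker. Day 20 cluster 3 was basal epithelium-like, with 7 markers, ITGA6, a laminin-binding integrin, at 5.23 among them. Day 10 cluster 16 was mesenchyme-like, with COL1A2 at 8.77, PDGFRA at 1.32 and APOE at 12.5. Clusters are not replicates, and no comparison of their sizes between days was made.

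Day 20 cluster 7 carried no name. It had 7 enriched ductal and 5 conjunctival markers, but its top 10 genes held 1 ductal marker, WFDC2, and 1 acinar marker, AQP5, so that no cell type list led. Of the other top genes, S100A9, S100A8, LCN2, DEFB1 and S100A7 were on the tear film and mucosal antimicrobial list, a gene group that was not used for names. It was led by S100A9 at 201, S100A8 at 68.0 and LCN2 at 40.1, against means of 0.0984, 0.0311 and 0.123 over the other day 20 clusters. DEFB1, an epithelial defensin, was at 4.80, WFDC2, a secreted protein of ducts, at 4.50, and AQP5, the water channel of lacrimal acini and ducts, at 4.59 against 0.0418. KRT5 was at 23.3 there and 62.2 elsewhere, and KRT19 at 70.6 and 95.1.

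**Figure D4:**
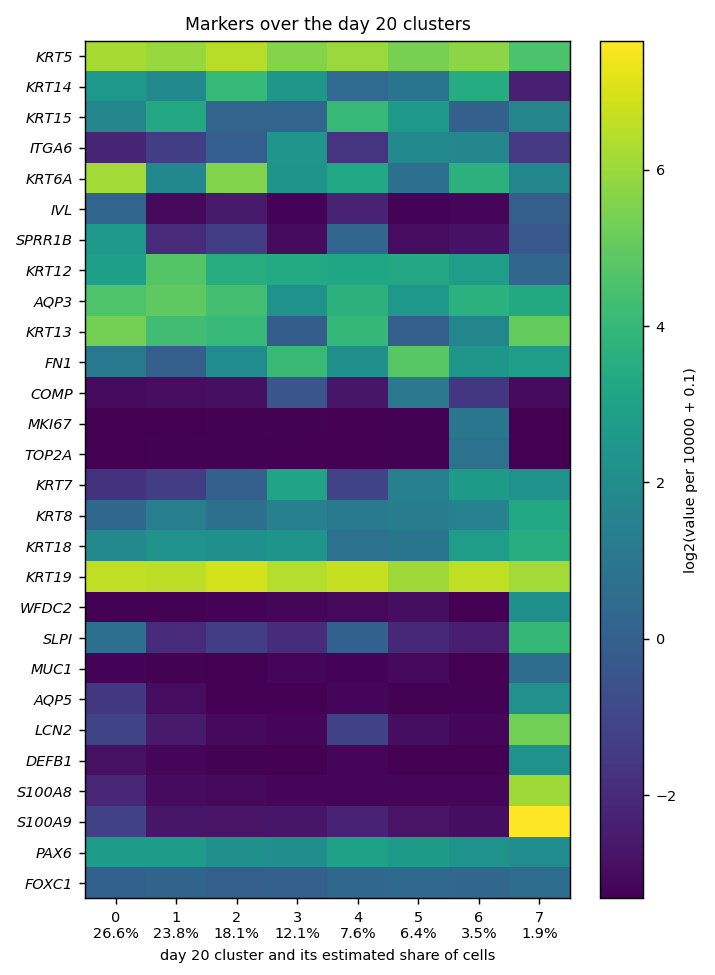
Log2 of the value per 10000 plus 0.1 (colour) of marker genes in the 8 day 20 clusters (horizontal axis, with estimated share of cells). Cluster 7, at 1.86% of cells, held AQP5 at 4.59, LCN2 at 40.1 and S100A9 at 201, and cluster 0 held KRT6A at 68.9.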

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

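Weighting by estimated shares, centring, leaving out day 10 cluster 11 and the length corrections were chosen after the data were seen. The length-matched random lists replaced a subtraction of the length trend from list members, whose calls had been seen and which shifted genes below the floor. Of 2140 values of named genes over the alternatives that apply to them, 2108 stayed at least 2-fold in their direction, 32 lost 2-fold and 0 turned. These genes were picked for clusters that did not overlap between the days, so no average over clusters could turn them. Leaving out single clusters gave 1440 of the values, all of which stayed. The larger pseudocount took 17 of 60 named genes below 2-fold. Of 3390 list values, 3162 kept their call or lack of one, 115 lost a call and 104 gained one. The other 9 moved to the other side of the median of their random lists, which was counted for called lists only. A median of opposite sign, whatever its random lists, was found in 22 of the 1626 values of called lists. Counting each list in each comparison, 44 of 91 were called, and 19 of these kept the call under every setting run. Of 467 recomputed counts, 422 stayed within 1.5 times the main count. Rescaling the columns moved nothing, since they already had one total. Unknown depth and 1 library per day limit every value. Weighting by given cell numbers and columns naming the day were not run.

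Counts below are for day 10 against day 0, day 20 against day 10 and day 20 against day 0, higher then lower in each. A pseudocount of 1 per 10000 gave 93 and 26, 31 and 15, and 80 and 42. No floor gave 667 and 209, 93 and 318, and 447 and 475, since more genes entered, and a floor of 10 per 10000 gave 18 and 9, 23 and 4, and 23 and 11, since fewer did. The 4-fold threshold gave 72 and 10, 7 and 3, and 56 and 20. Centring gave 50 lower for day 10 against day 0, 80 higher and 70 lower for day 20 against day 10, and 88 lower for day 20 against day 0. Removing the length trend with the median shift gave 71, 39 and 75 lower. With the median kept these were 124, 72 and 185, so that the falls for day 10 and day 20 against day 0 came with centring, and 150 were higher for day 10 against day 0. Lists called moved to 4 higher for day 20 against day 10 with the median over clusters. With members at the floor they moved to 1 lower for day 10 against day 0, and to 3 higher and 2 lower for day 20 against day 10. With the mean of members they moved to 7 lower for day 20 against day 0. Named clusters went from 9 to 4 against the highest other cluster and to 1 with the higher floor. Lists with day ranges apart went from 3 to 6, 2 to 4 and 5 to 11 without the farthest cluster. Where no construction is named, the cause was not tested.

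Sides turned against random lists for the conjunctival list for day 20 against day 0 with the median over clusters (-0.036), and for day 20 against day 10 with members at the floor for the ductal (-0.044) and fluid transport lists (-0.17). Leaving out each cluster in turn gave 1 to 3 lists lower for day 10 against day 0 and 3 to 10 lists higher for day 20 against day 10. The same gave, for day 20 against day 0, -1.71 to 0.97 for proliferation, -0.053 to 0.93 for conjunctival and -0.022 to 2.68 for tear film genes. For day 20 against day 10 it gave -0.12 to 0.32 for ductal, -0.071 to 0.31 for conjunctival and -0.14 to 2.35 for tear film genes. The lowest of these list medians, other than that of proliferation, came without day 20 cluster 7, whose part in the tear film shift was tested. For the other lists the cause was not tested.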

Other observations

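The tests of a few clusters, of one small cluster and of immune cells were chosen only after the result was seen. Day 0 cluster 5, an estimated 6.32% of the day 0 cells, was led by FABP4, a fatty acid binding protein, at 20.6 per 10000, with PMP2, a myelin protein, at 2.75, COL1A2, a collagen chain, at 3.14 and CRYAB, a small heat shock protein, at 3.78. The top 10 genes of day 0 cluster 5 also held KRT12 at 11.04 and KRT7 at 7.16. This cluster carried no name, with 3 corneal, 2 myoepithelium and 2 mesenchyme markers enriched. On day 10, FABP4 at 5.03, PMP2 at 1.76 and COL1A2 at 8.77 led cluster 16, the mesenchyme-like cluster, an estimated 0.914% of cells. Day 10 cluster 11 (2.81%) held the nuclear noncoding RNAs MALAT1 at 1019 and NEAT1 at 237, against 228 and 42.0 over the other clusters. It also had the highest mitochondrial share of the day 10 clusters, 17.05% against a mean of 12.5%. Its ribosomal protein share was the lowest, 5.29% against a mean of 14.4%. Whether cell quality set this cluster apart was not tested. Day 10 cluster 12 was led by HOPX at 9.11, SPRR1B at 10.6 and IVL, which encodes involucrin, at 4.25. Day 10 cluster 13 held S100A9 at 52.0, S100A8 at 6.50 and SLPI, a mucosal protease inhibitor, at 2.08. Day 10 cluster 18 (0.0932%) was led by the chemokine CXCL10 at 1.82.

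Of the genes listed on a single day, 482 were on day 0, 446 on day 10 and 155 on day 20, and none reached 1 per 10000 in any cluster. The highest were LY6H at 0.328 on day 0, CXCL5 at 0.127 on day 10 and SAA1, an acute phase protein, at 0.817 on day 20. Of the 24 clusters of the whole series, 6 were closest by rank correlation across genes to a day 0 cluster, 14 to a day 10 cluster and 4 to a day 20 cluster, with a median rho of 0.996 and a lowest of 0.817. Over genes at the floor 19 of the 24 kept the same closest cluster, with a lowest rho of 0.759.

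Short transcripts were lower and long transcripts higher on day 10 than on days 0 and 20. Spearman's rho with transcript length was 0.49 for day 10 against day 0 (0.38 to 0.63 over single day 10 clusters) and -0.56 for day 20 against day 10, which describes the pattern and tests no explanation of it. More intronic RNA in the day 10 library is a candidate explanation, since the partial rank correlation with intron length given transcript length was 0.13. This stays open, as do a length bias of library preparation and a biological difference between the days, which were not separated, since each day is 1 library.

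Early response genes were higher on days 10 and 20 than on day 0. A rise of heat shock genes as a set was not seen. For day 10 against day 0 their median log2 ratio was 0.020 over 11 genes, beside 1.89 for the early response list. The early response list also holds 2 of them, HSPA1A and HSPA1B. Members ran from -1.20 (HSPE1) to 1.12 (DNAJB1), and 1 was at least 2-fold higher. A median over so wide a spread cannot exclude a heat shock response carried by some of these genes. A few clusters as the source were argued against by the gap of 1.02 log2 units between the lowest day 10 and the highest day 0 list mean. Dissociation stress without heat shock, which the early response list was also drawn up to cover, was not tested. Other handling differences between the libraries and the culture day itself stay open as untested.

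Tear film and mucosal antimicrobial genes were higher on day 20 as a list, of which 10 of 18 genes were measured. LTF, LCN1 and PIGR were not among these, and LYZ was at 0.0032 on day 20, with a log2 ratio of 0.038 against day 0. One small cluster may account for the shift, since the list median for day 20 against day 0 was 2.51 with day 20 cluster 7 and -0.022 without it. Without that cluster SLPI (1.97) and LCN2 (1.07) kept log2 ratios above 1, while S100A9 (-1.92) and S100A8 (-1.58) turned lower. The day means of these genes were then below the floor on both days. On day 0, S100A9 and S100A8 were highest in cluster 3, at 4.43 and 1.89. Their means over the other day 0 clusters were 0.110 and 0.0626, beside 0.0984 and 0.0311 on day 20 without cluster 7. Immune cells as the source were argued against. Besides LYZ, which the acinar and tear film lists also hold, 4 immune markers were measured. The highest in day 20 cluster 7 was CD68 at 0.308, above its mean of 0.0392 over the other day 20 clusters. In cluster 7, PTPRC, CD79A and FCER1G were at 0 and KRT19 at 70.6. Whether a secretory epithelial state or another epithelial type forms the cluster was not tested.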
